A study of Arabidopsis thaliana with 12 samples.

How the data were processed

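RNA-seq was made from Arabidopsis seedlings, wild type Col-0 and an atg5 insertion line, germinated for 5 days in NM or WSM. Libraries were made with a stranded mRNA kit and sequenced in pairs on an Illumina instrument, per the labels' protocols. Per the submitters' processing notes, bcl2fastq, Bowtie2, bedtools and DESeq2 were used with the TAIR10 genome. Their versions and settings are not given in the sources used here.

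The authors deposited a table per genotype, with raw counts per gene and library. The same deposited tables hold the authors' log2 fold changes and their standard errors, test scores, p-values and adjusted p-values, per the file headers. Another 10 columns of normalized values per library were not used. The wild-type table lists 20002 genes, that of atg5 lists 20492, and 19714 are in both. Every listed gene had more than 1 CPM in at least 2 libraries, so low genes had been removed before deposit. The 10 count columns name a genotype, a medium and a number. The numbers differ from those of the 12 titles, so each column was given its group but no title, and 2 labelled samples have no column used here. Counts were summed without regard to strand: of 630 genes with more than 100 counts and at least 90% of their exons inside exons of an opposite-strand gene, 624 had counts at most 1.1 times those of the partner, and AT2G34420 and AT2G08665 had the same total of 596977. Overlapping and antisense genes are therefore uncertain. All 20780 row names matched the TAIR10.1 RefSeq annotation, from which symbols, positions and exonic lengths were taken.

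The 10 libraries held 8928632 to 24022759 counts, and 25 genes in the rRNA regions held 19.0% to 65.5% of each. Counts of all 19714 genes in both tables were fitted in 1 edgeR quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors and 4 groups, leaving 6 residual degrees of freedom and a biological coefficient of variation of 28.2%. The filter filterByExpr removed 0 genes. The 288 genes listed only for wild type and the 778 listed only for atg5 lay outside this fit. A gene missing from either table could therefore not be called between the genotypes. Contrasts were WSM against NM in each genotype, the difference of these responses, and atg5 against wild type in each medium. The count of 10 libraries replaces the 12 of the planned fit, and Benjamini-Hochberg adjusted p under 0.05 was a call. CPM values use TMM-scaled totals. SE is the standard error of a log2 fold change, derived from the quasi-likelihood F statistic. With 1 to 3 counts in a group a fitted fold is unstable, so levels or counts are given.

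Named genes followed a rule fixed before the data were examined. It takes a set of marker genes in each contrast, the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and groups that did not overlap, and up to 3 called members of each list. The 21 fixed lists were autophagy, abscisic acid, water deficit, LEA, seed storage and oil body, storage lipid mobilisation, photosynthesis, senescence, salicylic acid and defence, oxidative stress, heat shock, endoplasmic reticulum stress, hypoxia, carbon starvation, flavonoids, aquaporins, cell division, expansins, root hair, endodermis and other root cells, and guard cells. They hold 305 distinct measured genes. Of 357 entries 10 were dropped because the reference annotation did not pair their locus with their symbol. Among these were ATG1A, ATG1B, ATG1C, ATG4A, ATG4B, ATG13A, ATG13B and ATG16 of the autophagy list. The 308 entries used were also in both deposited tables. Others were not, among them PR2, PR5, SAG12, SAG13, RD20, COR15A, HAI1 and NCED9. Counts of list members therefore leave out genes missing from either table. The lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. They were also tested with fry, which tests whether a list's genes move on balance one way. With an estimated correlation 0 lists passed in any of the 5 contrasts.

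Alternatives were DESeq2 1.42.0, RLE size factors, no filter, only the groups compared, a fold threshold, and each library left out in turn. The planned block by the number in the titles was not run, since the titles could not be matched to columns. Alternatives chosen after seeing the data were the column number as a block, length and GC correction, leaving out rRNA-region genes, leaving out the 2 libraries richest in them, leaving out the 2 atg5 WSM libraries with PREP1 counts, fitting each table alone, and leaving out each library in turn for the lists. Where a setting leaves a group with 1 library, its spread is taken from the other groups. Alternatives for normalized values were not run, since the tables hold counts. The code was tested on simulated counts for 19714 genes. Of 100 genes changed by a log2 of 2 it recovered 71%, 66%, 14%, 67% and 72% in the wild-type, atg5, difference, NM and WSM contrasts, and of 100 changed by a log2 of 1 it recovered 9%, 10%, 0%, 3% and 13%. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.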

Results

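Gene-level RNA counts were obtained from Arabidopsis thaliana seeds germinated for 5 days in liquid culture. Wild type was Col-0, and atg5 was an insertion line for ATG5, a protein needed to attach ATG8 to lipid during autophagy, the vacuolar recycling of cell contents. Control medium (NM) held 0.5% sucrose, and the water stress medium (WSM) also held 2.5% glycerol and 0.5% alginic acid. The labels describe 12 samples, 3 in each of 4 groups, and the count columns cover 10 of them: 3 wild-type NM, 2 wild-type WSM, 2 atg5 NM and 3 atg5 WSM libraries. The growth protocol read here breaks off in mid-sentence, and the part before that does not say whether replicates came from separate flasks. The p-values therefore measure only the spread between these samples, which may be technical. In the joint fit each gene has a single spread, shared by the 4 groups. Log2 counts of replicate pairs correlated at 0.97 to 0.98 in wild type and at 0.86 to 0.94 in atg5. Counts of calls in wild type and atg5 therefore do not compare the size of their responses. Libraries are named here by group and by the number in their column.

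Library totals ran from 8928632 to 24022759 counts. Genes in the rRNA regions took between 19.0% (atg5 WSM library 2) and 65.5% (wild-type NM library 2 and atg5 WSM library 1) of them. The shallowest library, atg5 WSM library 1, held 3079573 counts outside these regions, and the other 9 held 7367768 to 16646054. It stood apart on the second principal component, at 114, while the other libraries lay between -42.7 and 24.3. Between replicate pairs the chi-square per degree of freedom was 30.5 to 386. It scales by totals that include the rRNA regions, so a difference in their share adds to it. It therefore does not measure the spread of other genes alone.

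**Figure D1:**
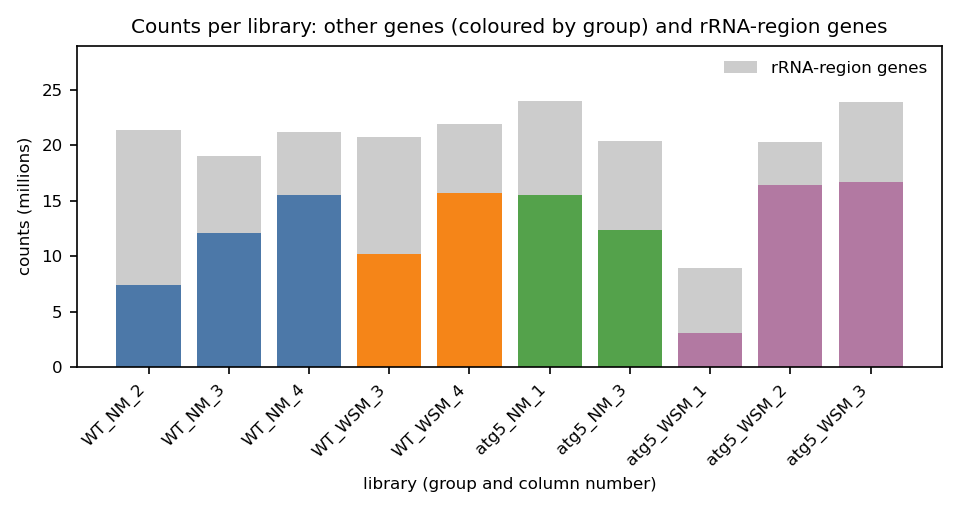
Stacked bars give the counts of each library, with genes outside the rRNA regions coloured by group and rRNA-region genes in grey. The bar of atg5 WSM library 1 reaches 8928632 counts, of which 3079573 lie outside the rRNA regions.

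ATG5 (AT5G17290, chromosome 5, 5686135 to 5689947, minus strand, TAIR10.1) was counted in every library. Its level was 29.1 ± 1.67 CPM in wild-type NM (SD, n = 3), 20.2 and 23.7 CPM in the 2 wild-type WSM libraries, 23.8 ± 4.66 in atg5 NM (n = 2) and 29.7 ± 2.95 in atg5 WSM (n = 3). The log2 difference between atg5 and wild type was -0.29 ± 0.20 (SE) in NM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.56) and 0.43 ± 0.21 in WSM (adjusted p = 0.435). Of its exons 27.6% lie in those of the antisense gene AT5G17280, so its level is uncertain. A count over the whole gene cannot show an insertion and so does not check the genotype, which is why these are called libraries labelled atg5.

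The libraries labelled atg5 did not share one state at a place on chromosome 3. PREP1 (AT3G19170, 6625377 to 6632164, minus strand), a peptidase of mitochondria and chloroplasts, had 2 and 0 counts in atg5 NM libraries 1 and 3 and 4 counts in atg5 WSM library 2. It had 349 and 2412 counts in atg5 WSM libraries 1 and 3, and 753 to 2668 counts in the wild-type libraries. PARC6 (AT3G19180, 6632637 to 6637292, plus strand), a chloroplast division protein encoded next to it, had 0 counts in the first 3 of these libraries, 15 and 175 in the other two, and 77 to 270 in wild type. ATG2 (AT3G19190, 6639639 to 6648870, plus strand), an autophagy protein encoded next to PARC6, stood at 31.1, 23.8 and 26.6 CPM in atg5 NM library 1, atg5 NM library 3 and atg5 WSM library 2. In atg5 WSM libraries 1 and 3 it stood at 8.66 and 6.32 CPM, against 3.12 to 10.02 CPM in the wild-type libraries. These genes were singled out after their values were seen. Both NM libraries but only 1 of the 3 WSM libraries labelled atg5 lacked PREP1 counts, so this state is mixed with the medium in every comparison that uses both, and with genotype in NM.

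**Figure D2:**
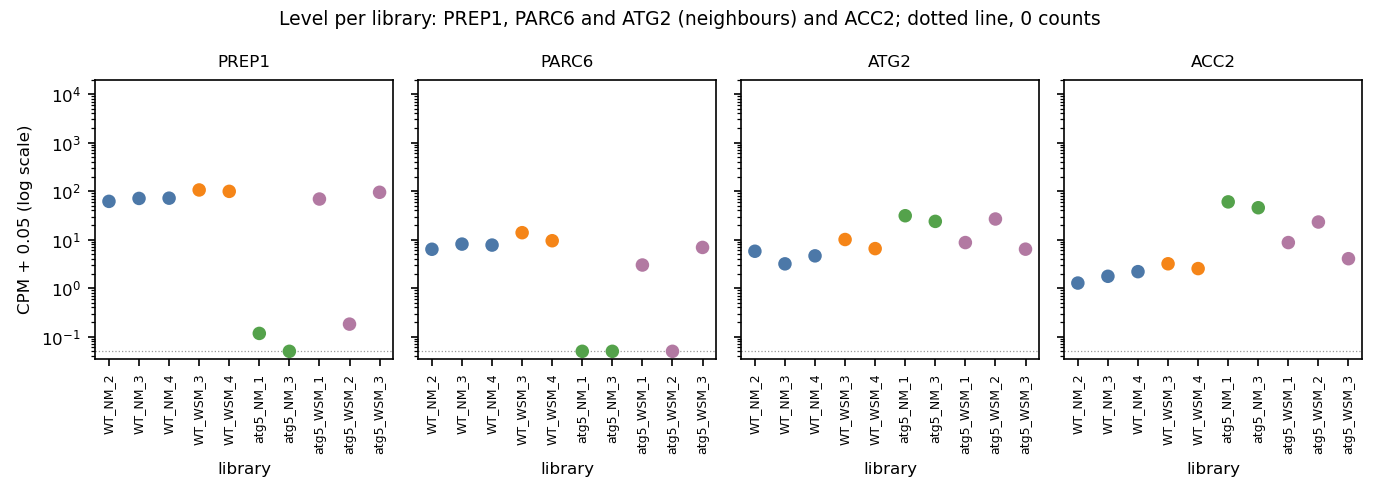
Points give the level of PREP1, PARC6, ATG2 and ACC2 in each library as CPM + 0.05 on a log axis, coloured by group, with a dotted line at 0 counts. PREP1 and PARC6 lie at or near the dotted line in both atg5 NM libraries and in atg5 WSM library 2.

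The first comparison asked how wild-type seedlings differed between the media. NCED3 (AT3G14440), the rate-limiting enzyme of abscisic acid synthesis, rose in WSM by a log2 fold change of 3.20 ± 0.56 (SE), from 0.672 ± 0.176 CPM (SD, n = 3) to 6.41 ± 1.43 CPM (n = 2; edgeR quasi-likelihood, adjusted p = 0.00707). CYP707A3, which breaks abscisic acid down, rose by 2.28 ± 0.39. The zinc finger factor ZAT10 rose from 6.51 ± 3.38 to 103 ± 2.48 CPM, the NADPH oxidase RBOHD by a log2 of 2.52 ± 0.37, and the drought factor DREB2A by 2.33 ± 0.47. The vacuolar aquaporin TIP1;2 fell from 1250.2 ± 248 to 239 ± 74.0 CPM, a log2 of -2.38 ± 0.37 (adjusted p = 0.00338). In all, 1161 of 19714 genes were called, 644 higher and 517 lower in WSM. This balance depended on the setting. DESeq2 called 998 higher and 1173 lower, and a fit of only the wild-type libraries 2777 and 3009. Without wild-type NM library 2, 3 or 4 there were 336 and 62, 327 and 112, or 378 and 160. The call of NCED3 was lost without wild-type WSM library 4 (adjusted p = 0.0631), those of TIP1;2 and CYP707A3 without library 3 (0.0769 and 0.103), and that of DREB2A without any 1 of the 5 libraries (0.0504 to 0.148).

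Among the fixed lists, the salicylic acid and defence list had 4 of 11 members called up and 0 down, also 4 and 0 when adjusted over the list alone, with a median log2 of 0.57 (camera adjusted p = 4.58e-05, or adjusted p = 0.292 with an estimated correlation). GRX480, WRKY70 and EDS1 rose by 5.04 ± 0.64, 3.13 ± 0.49 and 1.41 ± 0.29. Of 16 oxidative stress genes 3 were called up (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0123, or adjusted p = 0.587 with an estimated correlation), namely ZAT10, OXI1 and RBOHD. Senescence genes had 3 of 11 called up, WRKY6, SAG14 and WRKY53, the last uncertain since 20.5% of its exons lie in those of an antisense gene (4 up and 2 down adjusted over the list alone; camera adjusted p = 0.0200, or adjusted p = 0.465 with an estimated correlation). The hypoxia list had a median of 1.03 with 1 of 11 called up, PDC1 (1 adjusted over the list alone; camera adjusted p = 0.0454, or adjusted p = 0.951 with an estimated correlation), a passing that was lost without the libraries richest in rRNA-region counts (adjusted p = 0.0920), and without wild-type NM library 2 or 3 or WSM library 4 (0.0584, 0.0824 and 0.530, the last with a median of 0.61). The defence, oxidative stress and senescence lists passed without any 1 of the 5 libraries. PDC1, at a log2 of 3.68 and 2.18 without wild-type WSM library 4, lost its call without any 1 of the 5 libraries (adjusted p = 0.0718 to 0.360), SAG14 without wild-type WSM library 3 (0.0656), and EDS1 without that one or any 1 NM library (up to 0.190).

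Aquaporins, the water channels of membranes, lay on the lower side in wild type. All 19 members were lower in WSM, 7 were called down and 17 were down when adjusted over the list alone, with a median of -1.18 (camera adjusted p = 2.72e-12, or adjusted p = 0.465 with an estimated correlation). TIP2;2, PIP2;4 and TIP2;3 fell by 1.81, 1.96 and 1.72 on the log2 scale. Of 7 markers of endodermis and other root cells 3 were called down (5 adjusted over the list alone; median -1.10, camera adjusted p = 1.72e-04, or adjusted p = 0.292 with an estimated correlation), among them CASP1, which builds the Casparian strip. PIP2;4 and TIP2;3 belong to this list and to the aquaporins. The 8 root hair markers had a median of -1.34 with 0 called by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.0389, or adjusted p = 0.914 with an estimated correlation). Guard cell markers had 1 of 7 called down, the stomatal peptide EPF2 (2 adjusted over the list alone; median -0.66, camera adjusted p = 0.0266, or adjusted p = 0.587 with an estimated correlation). The flavonoid list of 12 had a median of -0.60 and 0 called, also 0 adjusted over the list alone (camera adjusted p = 0.0266, or adjusted p = 0.587 with an estimated correlation), a passing lost after length correction (adjusted p = 0.0546) and without wild-type NM library 4 or WSM library 4 (0.0544 and 0.374, the last with a median of -0.37). The root hair list did not pass without wild-type WSM library 3 (0.0784) nor the guard cell list without NM library 4 (0.0535), while the aquaporin and endodermis lists passed without any 1 library. CASP1 and EPF2 lost their calls without any 1 of the 5 libraries (adjusted p up to 0.304 and 0.298), PIP2;4 and TIP2;3 without wild-type WSM library 3 (0.0675 and 0.0688), and TIP2;2 without 4 of the 5, all but NM library 4 (up to 0.213).

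Several classical water-deficit markers were not called in wild type. RD29A had a log2 of 0.19 ± 0.26, P5CS1 of 0.0747 ± 0.25 and RAB18 of 0.12 ± 0.59. The 23 water-deficit genes had 1 called up, DREB2A (1 adjusted over the list alone), and a median of 0.12 (camera adjusted p = 0.726). The abscisic acid list of 27 had 2 called up and 2 down, the receptors PYL5 and PYL6 (2 up and 4 down adjusted over the list alone; camera adjusted p = 0.765). Of 30 autophagy genes ATG18F was called up, at 1.47 ± 0.29, and ATG8A down, at -0.97 ± 0.24 (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.871). Late embryogenesis abundant (LEA) genes, seed storage genes, storage lipid mobilisation, photosynthesis and carbon starvation genes had medians of 0.0333, -0.38, -0.13, -0.0648 and 0.29, with 0 members called by edgeR and 0 adjusted over the list alone. Their camera adjusted p were 0.965, 0.344, 0.726, 0.726 and 0.652. Heat shock genes had a median of 0.85 (camera adjusted p = 0.128) and endoplasmic reticulum stress genes one of 0.11 (adjusted p = 0.726), again with 0 called and 0 adjusted over the list alone. Leaving out 1 library in turn gave medians of 0.33 to 1.18 for heat shock, -0.88 to -0.33 for expansin and -0.67 to -0.15 for seed storage genes. The heat shock list passed without wild-type WSM library 3 (camera adjusted p = 0.0112) and the photosynthesis list without WSM library 4 (median -0.48, 0.0109), though its median was 0.27 without WSM library 3. The cell division list had a median of 0.11 with PCNA1 called down (2 down adjusted over the list alone; camera adjusted p = 0.871, toward lower values), and the expansin list a median of -0.61 with TCH4 called up (1 up and 1 down adjusted over the list alone; camera adjusted p = 0.164). The calls of DREB2A, PYL5, ATG8A and PCNA1 were each lost without any 1 of the 5 libraries (adjusted p up to 0.148, 0.270, 0.290 and 0.197). That of PYL6 was lost without wild-type WSM library 3 (0.0994), that of TCH4 without it or NM library 2 or 3 (up to 0.158), and that of ATG18F without these or WSM library 4 (up to 0.107).

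The genes with the largest rises by the rule for named genes held several overlapping gene models. PP2-B13, an F-box protein gene, went from 0.396 ± 0.202 to 37.1 ± 14.4 CPM, and it shares exons with AT1G56242, so which of the pair was transcribed is uncertain. AT4G08985 went from 0.0255 to 25.4 CPM but lies inside the exons of AT4G34410, the stress factor gene RRTF1, and is equally uncertain. PP2-B14 went from 0.0870 ± 0.0822 to 22.7 ± 10.1 CPM. AT3G02840, which overlaps AT3G01165, and AT1G05675 rose by 6.71 ± 0.69 and 6.69 ± 0.63. The largest falls included TINY (tny in the reference), an AP2 factor gene, at -3.37 ± 0.64, AT3G20015 at -2.73 ± 0.46, and the arabinogalactan protein genes AGP14 and AGP21 at -2.60 ± 0.36 and -2.59 ± 0.28, the last with an antisense overlap that counting without strand cannot separate. Longer genes had higher fold changes in wild type (Spearman's rho = 0.38 across 19315 genes, which are not independent), with medians of -0.31 among genes of up to 1116 exonic bases and 0.37 among those of at least 2579. TINY lost its call without wild-type NM library 2 or either WSM library (adjusted p up to 0.147), and AT3G20015 without either WSM library (up to 0.0798).

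The count of 1161 fell to 398, 439 and 538 without wild-type NM library 2, 3 or 4, and to 272 and 415 without wild-type WSM library 3 or 4. It was 5786 when only the wild-type libraries were fitted, 2171 with DESeq2 and 2813 without the 2 atg5 WSM libraries with PREP1 counts. PCNA1, EPF2, CASP1, ATG8A and PDC1 also lost their calls after length correction (adjusted p up to 0.198), where the log2 of ATG8A went from -0.97 to -0.59, of CASP1 from -1.102 to -0.72 and of PCNA1 from -0.75 to -0.47, and without the libraries richest in rRNA-region counts (up to 0.132), and ATG8A and EPF2 after GC correction (0.0630 and 0.0713). The authors' deposited table listed 2457 genes higher and 2983 lower in WSM at an adjusted p under 0.05, which included all 1161 called here in the same direction. The authors' own calls, at an adjusted p under 0.01 and an absolute log2 of at least 2, were 394 higher and 168 lower. Of the 542 of these in both tables, 391 were called here in the same direction.

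The second comparison asked the same of the libraries labelled atg5. NCED3 rose by 3.46 ± 0.61 (edgeR quasi-likelihood, adjusted p = 0.00684), ZAT10 from 6.37 ± 1.21 (SD, n = 2) to 114 ± 44.2 CPM (n = 3), and WRKY70 and GRX480 by 4.11 ± 0.58 and 5.44 ± 0.71. The small heat shock proteins HSP17.6A, HSP17.6II and HSP17.4 rose by 3.84 ± 0.89, 3.58 ± 0.86 and 3.43 ± 0.79, the last uncertain since 62.6% of its exons lie in those of an antisense gene. The dehydrin LTI30 rose by 1.47 ± 0.26, and BIP1 (AT5G28540), a chaperone of the endoplasmic reticulum, fell from 323 ± 53.1 to 130 ± 26.7 CPM, a log2 of -1.31 ± 0.24 (adjusted p = 0.00855). In all, 1549 genes were called, 1029 higher and 520 lower in WSM. When only these 5 libraries were fitted 312 were higher and 8 lower, and with all genes listed for atg5 295 and 8. DESeq2 on all libraries called 1681 higher and 978 lower. The heat shock proteins had 73.5 ± 84.6, 41.6 ± 48.6 and 55.4 ± 58.5 CPM in WSM, SDs above their means, and their calls were lost without either atg5 NM library (adjusted p up to 0.112, 0.170 and 0.121). Without atg5 WSM library 3 their log2 values were 2.24, 1.94 and 2.05. BIP1 lost its call without atg5 NM library 3 (0.0697). When only these 5 libraries were fitted, 33 of the 49 calls of named genes were lost, among them those of NCED3 (adjusted p = 0.0669), LTI30 (0.101), BIP1 (0.142) and the 3 heat shock proteins (0.119 to 0.125). The 16 kept included ZAT10, GRX480, WRKY70 and CYP707A3, and with all genes listed for atg5 the call of DREB2A was lost too (0.0534).

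Water-deficit, LEA, heat shock, hypoxia and carbon starvation lists had positive medians in these libraries, while endoplasmic reticulum stress genes had a median of -0.31. Levels per library are given as a list's median log2 against its mean over all libraries. Water-deficit genes, which lay at -0.61 and 0.022 in NM libraries 1 and 3 and at 0.43, 0.24 and 0.34 in WSM libraries 1, 2 and 3, had 5 of 23 called up (6 adjusted over the list alone; median 0.80, camera adjusted p = 7.60e-04, or adjusted p = 0.299 with an estimated correlation), including DREB2A and ERD10, the latter at 0.93 ± 0.24. RD29B rose by 1.59 ± 0.44, while RD29A had -0.38 ± 0.26 and RAB18 0.85 ± 0.70, neither of them called. LEA genes, at -1.40 and -1.90 in NM and at 0.79, -1.55 and -0.71 in WSM, had 2 of 11 called up, LEA4-5 and LEA14 (2 adjusted over the list alone; median 1.22, camera adjusted p = 0.00247, or adjusted p = 0.453 with an estimated correlation). Heat shock genes, at -0.43 and 0.16 in NM and 0.99, 0.81 and 2.94 in WSM, had 3 of 9 called up (7 adjusted over the list alone; median 1.76, camera adjusted p = 0.00160, or adjusted p = 0.453 with an estimated correlation). Hypoxia genes had 2 of 11 called up, HRE2 and PCO1 (4 adjusted over the list alone; median 2.03, camera adjusted p = 0.00160, or adjusted p = 0.453 with an estimated correlation). Carbon starvation genes had 3 of 10 called up, among them SEN1 at 1.74 ± 0.39, with DIN6 at 3.15 ± 0.85 but at 1.70 without atg5 WSM library 3 (5 adjusted over the list alone; median 0.91, camera adjusted p = 0.00477, or adjusted p = 0.453 with an estimated correlation). Without atg5 NM library 1 the water-deficit, heat shock, hypoxia and carbon starvation lists did not pass (camera adjusted p = 0.135, 0.0531, 0.161 and 0.0744), with medians of 0.37 for water-deficit and 1.26 for hypoxia genes. The water-deficit median was 1.22 without atg5 NM library 3. Without atg5 WSM library 1 the LEA list did not pass (median 0.46, adjusted p = 0.134), and without library 3 the heat shock and carbon starvation medians were 0.54 and 0.36. Calls lost without atg5 NM library 1 were those of LEA14, ERD10, RD29B, HRE2, PCO1, SEN1 and DIN6, and those lost without atg5 NM library 3 were LEA4-5, LEA14, ERD10, RD29B, SEN1 and DIN6. Without atg5 WSM library 3 those of ERD10, RD29B, HRE2 and DIN6 were lost. The highest adjusted p were 0.119 for LEA4-5, 0.0735 for LEA14, 0.132 for ERD10, 0.233 for RD29B, 0.0983 for HRE2, 0.0785 for PCO1, 0.104 for SEN1 and 0.227 for DIN6.

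The hypoxia and LEA lists did not pass without the 2 libraries richest in rRNA-region counts (adjusted p = 0.0508 and 0.148). Leaving out atg5 WSM libraries 1 and 3, which hold PREP1 counts, leaves library 2 as the only atg5 WSM library, with a spread taken from the other groups, so its p-values describe that library. The hypoxia median was then -0.51 (adjusted p = 0.825), and the LEA and carbon starvation medians were -0.14 and 0.51 (adjusted p = 0.860 and 0.227). Of the 49 calls of named genes 20 were then lost, among them HSP17.4, HSP17.6II, ERD10, RD29B, HRE2, PCO1, SEN1 and DIN6 (adjusted p of these up to 0.338). The log2 of DIN6 was then 1.06, of HRE2 1.64 against 3.48, of PCO1 1.15 against 2.28, of SEN1 0.95, and of HSP17.6A, HSP17.6II and HSP17.4 2.01, 1.77 and 1.76. The heat shock and water-deficit lists passed at medians of 0.54 and 0.40 (adjusted p = 0.0336 and 0.00720), and the root hair list at -2.95. ERD10 and RD29B lost theirs without the libraries richest in rRNA-region counts as well (0.0712 and 0.0674), and ERD10 after GC correction (0.0752). Per library, the hypoxia genes lay a median log2 of 2.71 and 2.07 above their mean over all libraries in these 2 libraries, at -0.31 in atg5 WSM library 2, and at -0.77 and 1.25 in atg5 NM libraries 1 and 3. ADH1, the alcohol dehydrogenase, stood at 381 ± 434 CPM in NM (n = 2) and 534 ± 463 CPM in WSM (n = 3), SDs close to or above the means.

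The defence, senescence and oxidative stress lists also had members called up in these libraries. The defence list had 3 of 11 called up and 1 down (6 and 1 adjusted over the list alone; camera adjusted p = 6.04e-04, or adjusted p = 0.299 with an estimated correlation). CBP60G, a regulator of salicylic acid synthesis, went from 0.0820 ± 0.0213 to 8.36 ± 5.49 CPM, and PR1, the marker of that pathway, fell from 1.39 ± 0.641 to 0.280 ± 0.134 CPM. Senescence genes had 4 of 11 called up (5 adjusted over the list alone; camera adjusted p = 0.00160, or adjusted p = 0.299 with an estimated correlation), with SAG14 at 4.11 ± 0.75. Oxidative stress genes had 4 of 16 called up (5 adjusted over the list alone; camera adjusted p = 0.00160, or adjusted p = 0.336 with an estimated correlation), with ZAT12 at 3.36 ± 0.51. The last list lay at -0.38 and 0.16 in NM libraries 1 and 3 and at 0.0891, 0.57 and 0.25 in WSM libraries 1, 2 and 3, and did not pass without atg5 NM library 1 (adjusted p = 0.161). Photosynthesis genes had a median of 0.95, and 29 of 30 were higher, but 1 was called, the plastocyanin PETE1 at 1.22 ± 0.29 (1 adjusted over the list alone; camera adjusted p = 2.87e-06, or adjusted p = 0.453 with an estimated correlation), a median that was 0.60 without atg5 WSM library 3. The defence, senescence and photosynthesis lists passed without any 1 library. PETE1 lost its call after length correction (0.0533). PR1 lost its call without atg5 NM library 3 or atg5 WSM library 2 or 3 (adjusted p up to 0.178), PETE1 without either atg5 NM library or atg5 WSM library 3 (up to 0.109), and SAG14 without atg5 NM library 3 (0.0930).

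Cell division, aquaporin and root lists had negative medians, of which that of the aquaporins rested on 1 library. All 15 cell division genes were lower, with PCNA1 called (1 adjusted over the list alone; median -0.55, camera adjusted p = 0.00160, or adjusted p = 0.299 with an estimated correlation). Their median was -0.30 without atg5 NM library 1 (adjusted p = 0.102). Aquaporins had 2 of 19 called down, PIP2;4 at -1.61 ± 0.28 and TIP2;3 at -0.93 ± 0.25 (4 adjusted over the list alone; median -0.47, camera adjusted p = 0.00527, or adjusted p = 0.560 with an estimated correlation). Per library they lay at -0.36 and 0.68 in NM libraries 1 and 3 and at -0.010, -0.41 and -0.018 in WSM libraries 1, 2 and 3. Their median was 0.19 without atg5 NM library 3 (adjusted p = 0.809) and -0.79 without atg5 NM library 1, and without atg5 WSM library 2 they did not pass either (0.0752). TIP2;3, at an adjusted p of 0.0465, kept its call in 4 of 16 alternatives, and lost it with RLE size factors and without atg5 NM library 3 or any 1 atg5 WSM library (adjusted p up to 0.264). PIP2;4 and PCNA1 lost theirs without atg5 NM library 3 (0.0652 and 0.0639). Markers of endodermis and other root cells had PIP2;4 and TIP2;3 called down (4 adjusted over the list alone; camera adjusted p = 7.99e-04, or adjusted p = 0.299 with an estimated correlation). Root hair markers had a median of -1.56 and 0 called by edgeR, also 0 adjusted over the list alone (camera adjusted p = 0.00286, or adjusted p = 0.453 with an estimated correlation). Per library these 8 genes lay at 1.14 and 1.35 in NM and at 1.29, -1.37 and -2.51 in WSM libraries 1, 2 and 3. The root hair and endodermis lists passed without any 1 library. The root hair median was -3.35, -1.05 and -1.004 without atg5 WSM library 1, 2 or 3, and the endodermis median moved from -0.93 to -0.53 without atg5 NM library 3. Storage lipid mobilisation had 1 of 15 called down, MFP2 (1 adjusted over the list alone; camera adjusted p = 0.00556, or adjusted p = 0.456 with an estimated correlation), a passing lost after length correction (adjusted p = 0.0647) and without atg5 NM library 3 or atg5 WSM library 2 (medians -0.17 and -0.39, adjusted p = 0.263 and 0.0833). Of 30 autophagy genes ATG8F rose by 1.31 ± 0.24 (1 adjusted over the list alone, camera adjusted p = 0.0927, fry adjusted p = 0.0374). By fry the water-deficit, defence, senescence, oxidative stress, cell division and endodermis lists also passed (adjusted p = 0.0264 to 0.0331). The other lists that passed camera here did not pass fry (adjusted p = 0.135 to 0.222). The call of ATG8F was lost when only these 5 libraries or all genes listed for atg5 were fitted (adjusted p = 0.0838 and 0.0903). Seed storage genes had 1 of 16 called down, OLEO2 at -1.79 ± 0.46 (named after its values were seen), while their median was 0.51 (1 down adjusted over the list alone; camera adjusted p = 0.929, toward lower values). Abscisic acid genes had 3 of 27 called up, among them NCED3 and CYP707A3, and 2 down, among them PYL6 (3 up and 2 down adjusted over the list alone; camera adjusted p = 0.929). Endoplasmic reticulum stress genes had 1 of 9 called up, BZIP60, and 2 down, BIP1 and BIP2 (1 up and 3 down adjusted over the list alone; median -0.31, camera adjusted p = 0.119). Flavonoid, expansin and guard cell lists had medians of -0.40, -0.18 and -0.38 with TCH4 called up and 0 others (1 up adjusted over the lists alone; camera adjusted p = 0.241, 0.929 and 0.235). Lists that passed toward lower values without 1 library were seed storage (median -1.1002 without atg5 WSM library 1, adjusted p = 0.00151, but 1.39 without atg5 NM library 3), flavonoid (without atg5 NM library 1, 0.0302) and guard cell genes (without atg5 WSM library 3, 0.0258). Without atg5 NM library 3 the calls of MFP2, CYP707A3, PYL6, TCH4, BIP1, BIP2 and BZIP60 were lost, BIP2 and BZIP60 also without atg5 NM library 1 or atg5 WSM library 2 or 3, and MFP2 without the last. Their adjusted p reached 0.177, 0.0553, 0.0536, 0.113, 0.0697, 0.162 and 0.169.

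PREP1 was also called here, from 0.0335 CPM in NM to 54.5 ± 48.8 CPM in WSM, a mean over libraries with 349, 4 and 2412 counts that describes none of them. Among the largest falls, AIF1, ANL2 and AT1G14430 had 20.9 ± 19.2, 28.8 ± 29.8 and 19.0 ± 15.8 CPM in NM, with SDs close to their means. Without atg5 NM library 3 their log2 went from -2.54 to -1.03, from -2.35 to -0.46 and from -2.72 to -1.46. AIF1 lost its call without atg5 NM library 3 (adjusted p = 0.264), ANL2 without it or atg5 WSM library 3 (up to 0.466), and PREP1 without either atg5 NM library or atg5 WSM library 3 (up to 0.1497). Shorter genes had the higher fold changes (Spearman's rho = -0.26 across 19309 genes). The count of 1549 was 467 without atg5 NM library 3, and 2771, 2426 and 737 without atg5 WSM library 1, 2 or 3, while it was 320 when only these 5 libraries were fitted and 2659 with DESeq2. The authors' deposited table listed 826 genes higher and 211 lower at an adjusted p under 0.05, and 980 of the 1004 in both tables were called here in the same direction. The authors' own calls, at an adjusted p under 0.01 and an absolute log2 of at least 2, were 437 higher and 24 lower. Of the 435 of these in both tables, 434 were called here in the same direction.

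**Figure D3:**
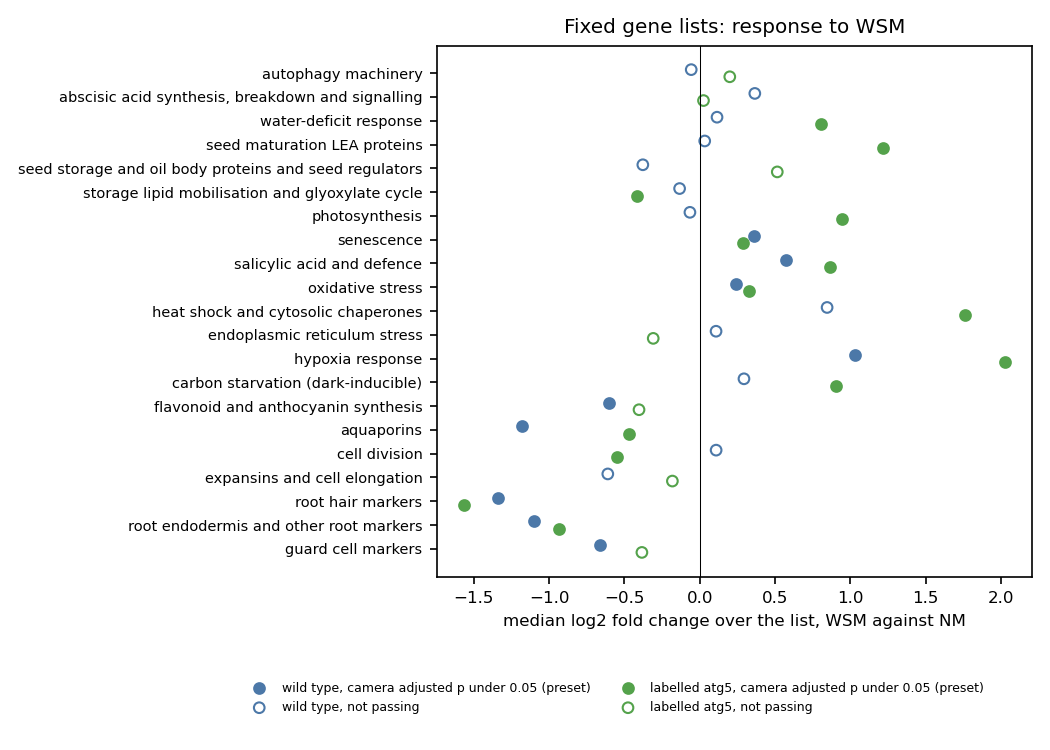
Points give the median log2 fold change of WSM against NM over each of the 21 fixed gene lists in wild type (blue) and in libraries labelled atg5 (green), filled where camera with its preset correlation gave an adjusted p under 0.05. Aquaporins lie at -1.18 in wild type and -0.47 in atg5 (0.19 there without atg5 NM library 3), and with an estimated correlation 0 lists passed in either.

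The third comparison asked whether the response to WSM differed between the genotypes. Across genes the 2 responses correlated (Pearson's r = 0.55, Spearman's rho = 0.33 over 19714 genes, which are not independent replicates), and the comparisons share no library. Of the genes called, 450 were higher in WSM in both, where independent lists would share 33.6, and 92 were lower in both, where 13.6 would be shared. Another 2 were called up in wild type and down in atg5, and 2 the reverse. Each gene has a single spread in the joint fit, so a gene of low spread is more readily called in both responses. The numbers given for independent lists may thus be too low as a chance level. Over the 2164 genes called in either genotype r was 0.80. Over all genes it was 0.39 without atg5 NM library 3.

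**Figure D4:**
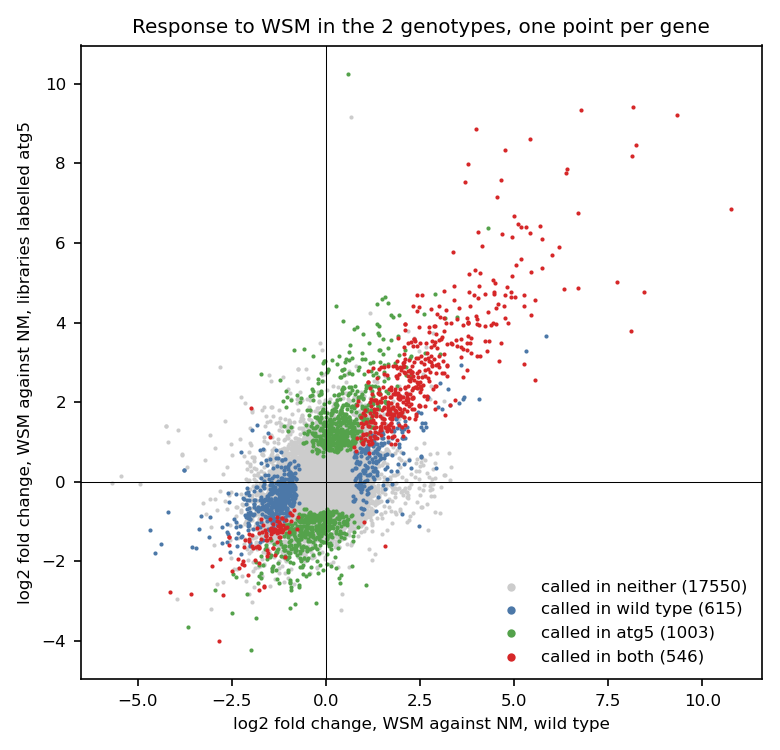
Each point is a gene, placed by its log2 fold change of WSM against NM in wild type (horizontal) and in libraries labelled atg5 (vertical), coloured by where it was called. The 450 genes called up in both lie in the upper right, and PREP1, whose fitted fold in atg5 rests on 2 and 0 counts in NM and is unstable, is the green point nearest the top.

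Calls for a difference of responses depended on the tool and on single libraries. With all 10 libraries edgeR called 0 of 19714 genes, with 2972 at an unadjusted p under 0.05, and DESeq2 called 414, 259 more positive and 155 more negative in atg5. The edgeR count was 53 without atg5 WSM library 2 and 1 without either atg5 NM library 1 or atg5 WSM library 1. By edgeR with all libraries, a gene called in 1 genotype alone is not shown to differ between them. The difference of responses (atg5 minus wild type, log2) was 1.36 ± 0.48 for TIP1;2 (adjusted p = 0.257), 1.32 ± 0.36 for LTI30 (0.200), 3.08 ± 1.13 for HSP17.6A (0.263), -1.42 ± 0.34 for BIP1 (0.194), 1.46 ± 0.33 for ATG8F (0.194) and 2.32 ± 0.48 for AGP14 (0.183). For EDS1 it was -0.55 ± 0.41 and for DIN6 3.49 ± 1.14. On simulated counts with a true log2 difference of 2, this test recovered 14% of 100 changed genes, against 71% for the wild-type response.

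As groups, 5 lists passed camera for a difference of responses. Photosynthesis (median 0.97), aquaporins (0.77), water-deficit (0.74) and LEA genes (1.21) were more positive in atg5, and cell division genes (-0.62) more negative. The camera adjusted p were 2.60e-07, 1.13e-04, 0.00531, 0.00599 and 0.00612, each with an adjusted p = 0.762 with an estimated correlation, and edgeR called 0 members, with 1 LEA gene adjusted over the list alone. Short genes lay on the positive side, with a median difference of 0.58 among genes of up to 1113 exonic bases and -0.60 among those of at least 2578 (Spearman's rho = -0.56 across 19417 genes). After length correction the LEA list no longer passed (adjusted p = 0.0776), nor did it without the 2 libraries richest in rRNA-region counts (adjusted p = 0.107), and with library 2 as the only atg5 WSM library the LEA and cell division lists had adjusted p = 0.935 and 0.0559. In atg5 NM libraries 1 and 3 the aquaporins lay at -0.36 and 0.68 and the water-deficit genes at -0.61 and 0.022. Without atg5 NM library 1 the aquaporin, water-deficit and cell division medians were 0.31, 0.30 and -0.30 (adjusted p = 0.163, 0.234 and 0.139), and without atg5 WSM library 1 the LEA median was 0.27 (0.138). The aquaporin median was 1.26 without atg5 NM library 3. Of the 5 lists 1, photosynthesis, passed without any 1 of the 10 libraries, with a median of 0.60 without atg5 WSM library 3. Another 10 lists passed without at least 1 library, namely autophagy, seed storage, storage lipid, heat shock, endoplasmic reticulum stress, hypoxia, carbon starvation, flavonoid, expansin and root hair genes. The lowest adjusted p among them was 1.59e-07, for root hair genes without atg5 WSM library 1 (median -1.65). In atg5 against wild type the NM and WSM medians were -0.96 and -0.0210 for photosynthesis and -2.24 and -1.36 for LEA genes. They were -0.30 and 0.37 for aquaporins, 0.0798 and 0.55 for water-deficit and -0.0573 and -0.54 for cell division genes. The photosynthesis difference thus went with a lower level in NM, where both atg5 libraries lack PREP1 counts, and not with a higher one in WSM.

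The fourth comparison set atg5 against wild type in NM. PAP85 (AT3G22640), a vicilin-like storage protein, had 50.7 ± 12.8 CPM in wild type (SD, n = 3) and 0.779 ± 0.818 CPM in atg5 (n = 2), a log2 of -6.11 ± 0.79 (edgeR quasi-likelihood, adjusted p = 0.0204). The oleosin OLEO2, of oil bodies, and LEA4-5 fell too, at log2 values of -3.03 and -3.10. CRU3, a cruciferin, stood at 605 ± 83.2 and 7.37 ± 6.31 CPM but was not called (log2 -6.37 ± 1.199, adjusted p = 0.0822). ACC2 (AT1G36180), a plastid acetyl-CoA carboxylase, was higher in atg5 at 52.8 ± 10.3 against 1.69 ± 0.458 CPM. PAP85, ACC2 and OLEO2 lost their calls without any 1 of the wild-type NM libraries, and OLEO2 also without atg5 NM library 1 (adjusted p up to 0.117, 0.117 and 0.119).

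Only genes listed for both genotypes could be called. Of these, 29 were called, 18 higher and 11 lower in atg5, with 2749 at an unadjusted p under 0.05. RLE size factors also gave 18 and 11, but other settings turned this balance. Fitting only NM libraries gave 104 higher and 136 lower, and DESeq2 gave 296 and 299. Without the libraries richest in rRNA-region counts it was 15 and 28, and without any 1 wild-type NM library 0 and 2. Of 16 seed storage genes 2 were called down (9 adjusted over the list alone; median -2.81, camera adjusted p = 2.41e-14, or adjusted p = 0.577 with an estimated correlation). Of 11 LEA genes 1 was called down (8 adjusted over the list alone; median -2.24, camera adjusted p = 1.21e-14, or adjusted p = 0.367 with an estimated correlation). The abscisic acid-responsive RAB18 and EM6 had -3.64 ± 0.72 and -3.67 ± 0.69, neither called. Photosynthesis genes had a median of -0.96 with 29 of 30 lower and 0 called (11 down adjusted over the list alone; camera adjusted p = 1.59e-17, or adjusted p = 0.646 with an estimated correlation). LHCB1.2, a light-harvesting protein, stood at 3068 ± 335 CPM in wild type and 1229 ± 172 CPM in atg5 (log2 -1.32 ± 0.38, adjusted p = 0.173). These 3 lists passed without any 1 of the 5 libraries, but not by fry (adjusted p = 0.280, 0.249 and 0.280).

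Heat shock and hypoxia genes had positive medians in atg5, at 1.34 and 1.95 and 0 called by edgeR (4 and 6 adjusted over the list alone; camera adjusted p = 0.00194 and 0.00347, each with an adjusted p = 0.653 with an estimated correlation). Per library the heat shock genes lay at -0.43 and 0.16 in atg5 NM libraries 1 and 3, against -1.45 to -1.04 in wild-type NM. The hypoxia genes lay at -0.77 and 1.25, against -1.91 to -1.16. Neither list passed without atg5 NM library 3 (medians 0.77 and 0.63, adjusted p = 0.0762 and 0.817), and camera's direction for hypoxia was then toward lower values. Storage lipid mobilisation (median 0.44), endoplasmic reticulum stress (0.29), flavonoid (-0.27) and aquaporin genes (-0.30) passed camera at adjusted p of 0.00265, 0.0405, 0.0266 and 0.00543, or adjusted p = 0.653, 0.653, 0.653 and 0.686 with an estimated correlation. Their calls adjusted over the list alone were 0, 3 up, 5 down and 2 down. The first, the flavonoid and the aquaporin lists did not pass after length correction (adjusted p = 0.0666, 0.0666 and 0.0526). Aquaporins lay at -0.36 and 0.68 in atg5 NM libraries 1 and 3 and at 0.49 to 0.62 in wild-type NM, and flavonoid genes at -0.29 and 0.40 against 0.25 to 0.42. Without atg5 NM library 1 the aquaporin median was 0.14 (adjusted p = 0.703) and the flavonoid median -0.15 (0.947), and without library 3 they were -0.90 and -0.79. The flavonoid list did not pass without wild-type NM library 4 either (-0.16, 0.0604). Storage lipid mobilisation did not pass without atg5 NM library 3 (median 0.27, 0.497), nor endoplasmic reticulum stress genes without wild-type NM library 2 or 3 or atg5 NM library 1 or 3 (0.0517 to 0.140). Water-deficit genes had a median of 0.0798 in NM and did not pass (adjusted p = 0.0717, toward lower values), but passed toward lower values without wild-type NM library 3 (0.0345) or atg5 NM library 3 (median -0.46, 2.08e-04), and had a median of 0.28 without atg5 NM library 1 (0.711). The abscisic acid and oxidative stress lists passed toward higher values without atg5 NM library 1 (0.00898 and 0.00543). Expansin and endodermis genes passed toward lower values without atg5 NM library 3 (0.0282 and 0.0331), and guard cell genes without wild-type NM library 3 (0.0320).

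ACC2, AT1G17960 and AT2G18193 had the largest rises, at 4.93 ± 0.59, 4.74 ± 0.67 and 3.88 ± 0.58. ACC2 stood at 60.0 and 45.5 CPM in the NM libraries and at 8.66, 23.1 and 4.004 CPM in WSM libraries 1, 2 and 3 labelled atg5. AT1G17960 stood at 19.4 and 17.3, then at 0.985, 9.58 and 2.55 CPM. AT2G18193 took another course, at 65.8 and 50.2, then at 17.5, 113.9 and 88.6 CPM, so it stayed high in WSM library 3. The calls of these 3 genes were lost without any 1 of the wild-type NM libraries, and that of AT2G18193 also without atg5 NM library 1 (adjusted p up to 0.117, 0.192 and 0.237). Longer genes were higher in atg5 in NM (Spearman's rho = 0.45 across 19212 genes). The count of 29 was 2 without any one of the 3 wild-type NM libraries and 75 without either atg5 NM library, 595 with DESeq2, 240 when only NM libraries were fitted, and 494 without atg5 WSM libraries 1 and 3.

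**Figure D5:**
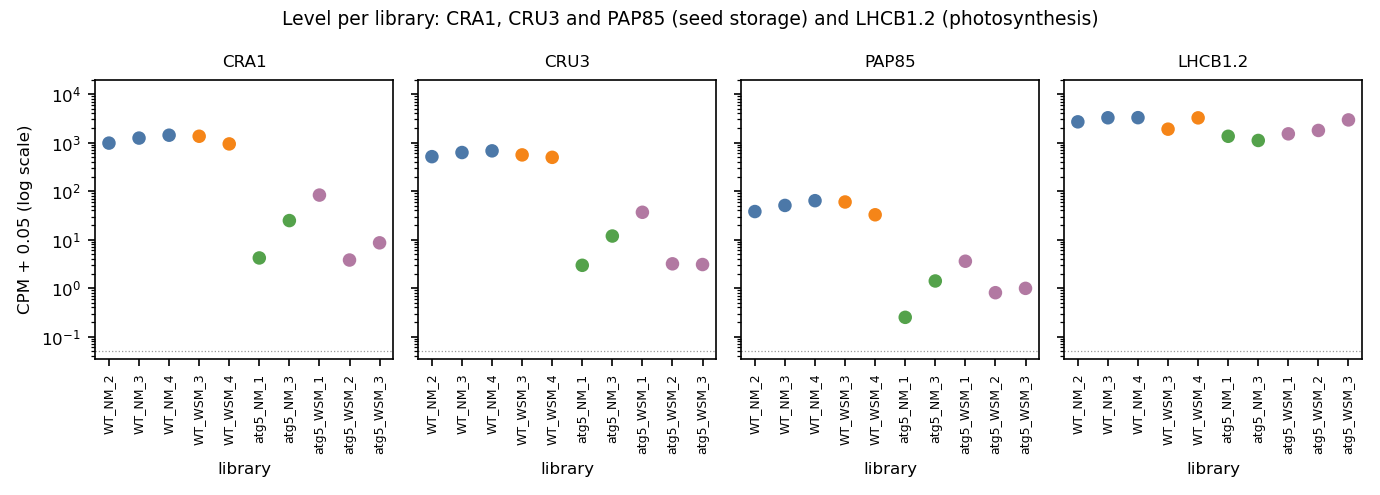
Points give the level of CRA1, CRU3, PAP85 and LHCB1.2 in each library as CPM + 0.05 on a log axis, coloured by group. CRA1 lies at 941 CPM or above in the 5 wild-type libraries and at 82.9 CPM or below in the 5 labelled atg5.

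The fifth comparison set atg5 against wild type in WSM. PAP85 had 46.1 ± 19.2 CPM in wild type (SD, n = 2) and 1.75 ± 1.56 CPM in atg5 (n = 3), a log2 of -5.12 ± 0.67 (edgeR quasi-likelihood, adjusted p = 0.0291). AT5G35660, AT1G54870 and AT3G54940 fell too, at -4.84, -3.79 and -3.15. OLEO2 at -4.12 and AT3G01570 at -2.90 were the other called falls, named here after their values were seen since their means were under 5 CPM. AT4G16260, annotated as a glycosyl hydrolase, was higher in atg5, at 37.0 ± 8.57 against 10.5 ± 1.104 CPM. In all, 7 of the genes listed for both genotypes were called, 1 higher and 6 lower, with 2367 at an unadjusted p under 0.05. This balance depended on the setting. DESeq2 called 281 higher and 62 lower. Without atg5 WSM library 2 edgeR called 166 higher and 31 lower, and without library 1 it called 30 and 32. PAP85, AT5G35660 and AT4G16260 lost their calls without either wild-type WSM library or atg5 WSM library 3 (adjusted p up to 0.307, 0.307 and 0.743), AT3G54940 without wild-type WSM library 3 or atg5 WSM library 3 (up to 0.245), and AT1G54870 without wild-type WSM library 3 (0.0834). When only the WSM libraries were fitted these 5 calls were lost (0.151 to 0.551), and AT4G16260 lost its call after length correction (0.0519).

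Seed storage genes had 2 of 16 called down (1 up and 9 down adjusted over the list alone; median -2.47, camera adjusted p = 3.32e-13, or adjusted p = 0.329 with an estimated correlation), and LEA genes had 0 called (1 up and 7 down adjusted over the list alone; median -1.36, camera adjusted p = 1.04e-05, or adjusted p = 0.407 with an estimated correlation). Per library the LEA list lay at 0.79 in atg5 WSM library 1, within the 0.66 to 1.27 of the 5 wild-type libraries, and at -1.55 and -0.71 in atg5 WSM libraries 2 and 3. All 9 heat shock genes were higher in atg5, 0 called over all genes and 9 adjusted over the list alone, with a median of 2.33 and per-library levels of 0.99, 0.81 and 2.94 in atg5 WSM libraries 1, 2 and 3 (camera adjusted p = 1.21e-08, or adjusted p = 0.329 with an estimated correlation). Autophagy genes had a median of 0.38 with 25 of 30 higher and 0 called, also 0 adjusted over the list alone (camera adjusted p = 4.23e-04, or adjusted p = 0.278 with an estimated correlation). By fry their adjusted p was 0.0498. The fry adjusted p of seed storage, LEA and heat shock genes was 0.303 each, that of hypoxia genes 0.331 and that of cell division genes 0.0590. Cell division genes had a median of -0.54 with 0 called and 2 down adjusted over the list alone (camera adjusted p = 3.20e-06, or adjusted p = 0.278 with an estimated correlation). Hypoxia genes had 0 called and 7 up adjusted over the list alone and a median of 2.02 (camera adjusted p = 6.11e-07, or adjusted p = 0.417 with an estimated correlation). Water-deficit, oxidative stress and aquaporin genes had medians of 0.55, 0.41 and 0.37 (camera adjusted p = 0.0253, 0.0158 and 0.00298, or adjusted p = 0.566, 0.537 and 0.769 with an estimated correlation), with 1 down, 0 and 0 adjusted over the list alone. These 3 lists did not pass without wild-type WSM library 3 (adjusted p = 0.116, 0.0515 and 0.563), nor did water-deficit genes without atg5 WSM library 1 (0.188) or oxidative stress genes without library 2 (0.127). The aquaporin median was 0.18 without wild-type WSM library 3 and 0.73 without library 4. The other 6 lists that passed did so without any 1 library, with medians of 1.16 for heat shock genes without atg5 WSM library 3, 3.19 for hypoxia genes without wild-type WSM library 4 and -3.76 for seed storage genes without atg5 WSM library 1. Per library the hypoxia genes lay at -0.99 and 0.12 in wild-type WSM and at 2.71, -0.31 and 2.07 in atg5 WSM libraries 1, 2 and 3.

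Photosynthesis genes had a median of -0.0210 in WSM (camera adjusted p = 0.505). It was -0.33 without wild-type WSM library 3 or atg5 WSM library 3 (adjusted p = 1.23e-04 and 9.43e-05) and 0.37 without wild-type WSM library 4 (0.0238), so its direction turned on single libraries. Carbon starvation genes passed toward higher values without wild-type WSM library 4 or atg5 WSM library 1 or 2 (adjusted p = 0.0299, 0.0169 and 0.00927), expansin genes without atg5 WSM library 2 (0.0498), and flavonoid genes toward lower values without wild-type WSM library 4 (0.0226). Root hair genes passed toward lower values without atg5 WSM library 1 (median -0.94, 1.25e-06) and toward higher values without library 3 (1.31, 0.0217). With library 2 as the only atg5 WSM library, and a spread taken from the other groups, the hypoxia median was -0.0496 (adjusted p = 0.792), the heat shock and LEA medians were 1.04 and -2.55 and their lists passed, and water-deficit and aquaporin genes did not pass (adjusted p = 0.344 and 0.299). Water-deficit genes did not pass without the 2 libraries richest in rRNA-region counts (adjusted p = 0.195). Shorter genes were higher in atg5 (Spearman's rho = -0.37 across 19207 genes). The count of 7 was 0 and 3 without wild-type WSM library 3 or 4, and 62, 197 and 1 without atg5 WSM library 1, 2 or 3. DESeq2 called 343, and edgeR on the WSM libraries alone called 0, with 1469 at an unadjusted p under 0.05.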

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

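The tests of seed storage transcripts and of PREP1 were chosen after their results were seen, as were length correction and leaving out 1 library as alternatives for lists, and the 3 tests of photosynthesis genes were written before.

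A difference of the WSM response between the genotypes marked 5 lists, as the median of atg5 minus wild type on the log2 scale. It was 0.74 for water-deficit, 1.21 for LEA, 0.97 for photosynthesis, 0.77 for aquaporin and -0.62 for cell division genes. After length correction the medians were 0.60, 0.66, 0.68, 0.53 and -0.33. Without atg5 NM library 1 the water-deficit, aquaporin and cell division lists did not pass (adjusted p = 0.234, 0.163 and 0.139), nor did the LEA list without atg5 WSM library 1 (0.138), while photosynthesis passed without any 1 library. Genes listed in a single table lie outside the joint fit, and when each deposited table was fitted alone, 56 of the 288 listed for wild type and 3 of the 778 listed for atg5 were called between the media.

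Photosynthesis genes had a median log2 of -0.96 in atg5 against wild type in NM, with 29 of 30 lower and 0 called by edgeR at an adjusted p under 0.05. Gene length bias as the whole cause was argued against, since the median was -0.79 after length correction, with a spread of 0.0642, against a bound of -0.5 set in advance. A single low atg5 library was argued against as well. Every wild-type NM library lay above both atg5 NM libraries with a gap of 0.83 (spread within groups 0.0862). The rRNA-rich wild-type NM library 2 lay lowest of its group, at 0.12 against 0.30 and 0.28 in libraries 3 and 4. It therefore did not raise the wild-type level, and leaving it out could only widen the difference. The median of -1.06 without the libraries richest in rRNA-region counts is thus no separate test. The genotype stays open as an explanation. So does the state at PREP1, since both atg5 NM libraries lack its counts, and no test here separates these.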

How the results depend on the processing

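Length and GC correction, the column-number block, fits of single tables, leaving out 1 library for the lists, leaving out rRNA-region genes and leaving out 2 libraries were chosen after seeing the data. The counts of called genes for the wild-type and atg5 responses, their difference, NM and WSM were 1161, 1549, 0, 29 and 7. With DESeq2 they were 2171, 2659, 414, 595 and 343. Fitting only the groups compared gave 5786, 320, 240 and 0 (no such fit exists for the difference), and all genes listed for a genotype gave 5833 and 303. Leaving out 1 library gave 272 to 538, 467 to 2771, 0 to 53, 2 to 75 and 0 to 197, where a lone library in a group is assumed to vary like the others. Without the 2 atg5 WSM libraries with PREP1 counts they were 2813, 1231, 0, 494 and 61, and without the 2 libraries richest in rRNA-region counts WSM had 36. GC correction gave 1 for the difference. The atg5 WSM libraries with PREP1 counts enter neither the wild-type nor the NM contrast. Without them those counts could move only through what the joint fit shares, its spread and its scaling. The causes of the other shifts were not tested.

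Whether the column numbers pair the samples could not be decided. Same-numbered libraries correlated in their deviations at 0.12 and 0.18 in wild type, where differently numbered ones reached 0.058. In atg5 they correlated at -0.29 and -0.0166, where differently numbered ones reached 0.35. In a group of 2 libraries the deviations mirror each other, so these correlations come with opposite signs and cannot exclude a pairing. With the number as a replicate block the counts were 360, 538, 0, 0 and 0 by edgeR, with 1890, 1512 and 1294 genes at an unadjusted p under 0.05 in the last 3. With this block 8 lists passed for the difference, and the photosynthesis list in WSM turned to 0.39 (adjusted p = 0.0108).

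Lists passing camera numbered 9, 14, 5, 9 and 9, against 0 in each with an estimated correlation and 4, 7, 0, 0 and 1 with fry. Leaving out 1 library gave 7 to 9, 9 to 15, 3 to 11, 8 to 10 and 7 to 12, and of the 9, 14, 5, 9 and 9 lists 5, 5, 1, 3 and 6 passed without any 1. Camera's direction turned without at least 1 library for 5, 5, 8, 10 and 9 of the 21 lists. Those that passed with all libraries or in the setting that turned them, with ranges of medians, were aquaporins in atg5 (-0.79 to 0.19) and NM (-0.90 to 0.14), hypoxia genes in NM (0.63 to 2.61), seed storage genes for the difference (-0.63 to 2.13), and photosynthesis (-0.33 to 0.37) and root hair genes (-0.94 to 1.31) in WSM. Among those that passed in neither were seed storage genes in atg5 (-1.1002 to 1.39), photosynthesis in wild type (-0.48 to 0.27) and water-deficit genes in NM (-0.46 to 0.28). For the difference, 11 passed without the libraries richest in rRNA-region counts and 8 without those with PREP1 counts. Without the rRNA-rich libraries the seed storage list turned to -0.50 for the difference and the root hair list to -0.95 in WSM. Without those with PREP1 counts the hypoxia list turned to -0.51 in atg5, -1.86 for the difference and -0.0496 in WSM, the seed storage list to -0.84 for the difference and the root hair list to -0.40 in WSM. The expansin list in WSM had a median of 0.0566 against 0.28, while camera's direction changed to lower. That setting leaves 1 atg5 WSM library.

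The correlation of the responses (0.55) was 0.80 over genes called in either genotype, 0.65 with length correction, 0.63 without the libraries with PREP1 counts and 0.39 to 0.64 leaving out 1 library. Its slope (0.58) was 0.88, 0.70 and 0.70 there, 0.72 without the rRNA-rich libraries, and 0.44 to 0.80. Over all alternatives the calls of named genes were unchanged in 2742 values, lost in 371 and gained in 58. The unchanged values include genes that had no call to lose. They also include 198 from the fit without a filter, which equals the main fit. Of the 2742, 93 in genes without a call had the opposite sign, and 0 called values did. Of 37, 49, 12 and 5 named calls in wild type, atg5, NM and WSM, 22, 30, 10 and 5 were lost without at least 1 library, and 0, 33, 0 and 5 when only the groups compared were fitted. ATG5 was not called in any. The shallow atg5 WSM library 1 held 3079573 counts outside the rRNA regions. Leaving it out raised the count of calls in WSM to 62, and leaving out the deeper library 2 raised it to 197. Low depth was therefore not shown to be what limits the atg5 contrasts in WSM.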

Other observations

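All tests in this part were chosen after the results were seen.

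Annotated processes were also compared between the media. Over 150 terms of 15 to 300 genes, camera passed 18 terms up and 9 down in wild type and 16 up and 14 down in atg5, and 0 in either with an estimated correlation. Response to chitin, a microbial elicitor, had 20 of 47 genes called up and 2 down in wild type (median 0.77, camera adjusted p = 6.41e-09, or adjusted p = 0.428 with an estimated correlation) and 22 up and 2 down in atg5 (median 1.201, camera adjusted p = 2.96e-13, or adjusted p = 0.104 with an estimated correlation). Innate immune response had 19 of 76 genes called up in wild type (camera adjusted p = 9.46e-11, or adjusted p = 0.635 with an estimated correlation) and 11 in atg5 (camera adjusted p = 0.00384, or adjusted p = 0.587 with an estimated correlation). Lipid transport had 14 of 62 genes called down in wild type (median -0.87, camera adjusted p = 1.36e-09, or adjusted p = 0.635 with an estimated correlation), and 1 up and 2 down in atg5. Its difference of responses had a median of 0.92 with 0 genes called by edgeR (camera adjusted p = 1.67e-07, or adjusted p = 0.513 with an estimated correlation).

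Seed storage genes had medians of -2.81 in NM and -2.47 in WSM in atg5 against wild type, with 2 of 16 called down in each and 2 and 4 of them higher. For CRA1 and CRU3, the 2 most abundant members, a few libraries with much seed RNA were argued against only by values already seen. The lowest wild-type library lay above the highest atg5 library by a log2 of 3.50 or more (spread 1.48). That gap describes the pattern and is no separate test. Over the whole list atg5 WSM library 1 lay at 0.48 and wild-type WSM library 4 at 0.60, a gap of 0.12 with a spread of 1.01, which leaves this explanation open for the other members. For one seed RNA profile present in different amounts, the members' log2 differences in NM had an SD of 2.33 against a median SE of 0.83, which goes against it, though transcripts that the seedlings make themselves could widen that spread. It stays open, since 0 members with at least 5 CPM in wild type were higher in atg5 in both media by more than 2 SE. A difference in the age or storage of the seed lots was not tested, and the genotype stays open too.

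PREP1 and PARC6 were near 0 in 3 of the 5 libraries labelled atg5. Low depth was argued against, since these 3 libraries held at least 12378302 counts outside the rRNA regions and the shallowest library with PREP1 counts held 3079573. CRA1 and CRU3 parted the libraries by their labels, with a gap of 3.50. This gap had been seen before the test was written, and it may follow seed lots rather than genotype. It therefore cannot decide whether wild-type and atg5 libraries were swapped in pairs. A change of the DNA at this place in some of the plants used may be a candidate explanation, since the genes lie side by side, but it was not tested, because sequence reads were not used here. The genotype alone leaves the difference between libraries labelled atg5 open.

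GMI1, NAC044 and NAC103 were singled out after their values were seen, so a likeness to the split at PREP1 is no separate evidence for it. In atg5 NM libraries 1 and 3 and atg5 WSM libraries 1, 2 and 3, GMI1 stood at 17.8, 15.3, 1.38, 16.2 and 4.08 CPM, NAC103 at 11.1, 7.71, 0.394, 13.2 and 2.43 CPM, and NAC044 at 6.46, 10.1, 2.17, 11.2 and 2.98 CPM. In the 5 wild-type libraries they stood at 2.45 to 4.19, 1.31 to 3.26 and 0.736 to 1.59 CPM. Among all genes, 9 lay under 0.5 CPM in an atg5 WSM library and at 20 CPM or more in another, PREP1 among them. Some split these libraries otherwise. In atg5 WSM libraries 1, 2 and 3 XTH12 stood at 28.6, 1.22 and 0.353 CPM and BRU6 at 2.76, 0.428 and 22.6 CPM.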
